A study of Mus musculus with 48 samples.

How the data were processed

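Whole blood of 48 female C57BL/6 mice was profiled on single-colour Agilent mouse arrays, 1 array per mouse, 3 mice in each of 16 groups. Per the labels, mice were irradiated whole-body in a small-animal irradiator at 1.05 Gy per min or sham-treated in the same container. RNA (Ribopure) was amplified from its poly(A) part over more than 1 round (MessageAmp II) and labelled through biotin. Groups were taken from dose, time and replicate number in the labels. Each array is a separate mouse per the labels, so gene p-values rest on spread between arrays.

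Per the file headers, Agilent Feature Extraction 11.5.1.1 turned each scan into spot values, on 1 channel, and the deposited intensity used here is its processed green signal on a linear scale. The steps inside that program are not given in the sources used here. Each array held 59305 spots that are no controls, and 0 were saturated. The authors' deposited value table holds intensity values of 30629 probes on a linear scale. Set against the scanner values, each of its columns was the same signal divided by 1 factor per array and floored at 0.01. For 24 of the 48 arrays that factor lay within 1 point of the 75th percentile of detected probes, and for the others its rule is not known. Between 0% and 44.4% of values (24 and 48 hr) and between 0% and 34.7% (6 and 16 hr) sat at the floor, and column medians were 0.015 to 0.062 and 0.024 to 0.133. The table was not centred per gene.

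The series used 2 versions of the array design, 1 for 24 and 48 hr and 1 for 6 and 16 hr, with 24 arrays each. They were normalized and fitted apart, and no level was set across them. The first holds 55681 probes, of which 27656 could be given 1 gene symbol and 28025 none, naming 20972 genes. The second holds 56605 probes, 32994 with a symbol and 23611 without, naming 22911 genes. Symbols come from the accession each file gives for a probe, matched without its version to a table of RefSeq genes (assembly GRCm38.p6), and unmatched probes kept their accession. The headers name another build, so no coordinates are given.

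The signal was taken as log2 after each array was divided by its 75th percentile. Only 1 of 48 arrays had at least 50% of its probes well above background, so the percentile was taken over the probes well above background on all arrays of a version (6524 and 6330). The plan named the percentile over all probes, with this one as its alternative. The 2 were exchanged after that share was seen, and the counts under both are given. The array's 75th percentile of signal ranged from 9.85 to 348 and from 15.1 to 140. Flagged outlier values were left out (378 probe values per version), and log2 values of the spots of a probe were averaged. A probe was kept if well above background on at least 3 arrays of its version. A gene's value is its kept probe with the highest mean over all arrays, and the mean of its kept probes was an alternative. This left 19064 features for 24 and 48 hr (12618 with a symbol) and 21932 for 6 and 16 hr (13721 with a symbol). Here "genes" counts features with and without a symbol.

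Each version was fitted as group means with limma 3.58.1 (lmFit, eBayes) in R 4.3.3, all 24 arrays sharing 1 estimate of the spread. Each of 12 irradiated groups was compared with the sham group of its time. Slopes of log2 signal per Gy were tested at 16, 24 and 48 hr. A contrast tested the mean effect of 2, 4 and 8 Gy at 48 against 24 hr. Another tested the 4 Gy effect at 16 against 6 hr. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided. Gene lists were tested with limma's camera, over genes with a value on every array, at a preset correlation of 0.01, adjusted over 288 tests, and again with a correlation estimated per list. That test compares a list with all other genes, so it can differ in sign from the list's median. A gene not well above background on any array of a group was given a bound: the brighter group's mean against the dimmer group's mean of, per array, the higher of its own value and the lowest signal among probes well above background. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the reading, permutation tests and figures.

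The groups, tests, gene lists, the alternatives not named below as added and the rule for naming genes were set before the data were examined. The rule takes, in 4 comparisons (4 Gy at 6 hr and 8 Gy at 16, 24 and 48 hr), the 10 genes in each direction with the largest change among those with adjusted p under 0.05 whose 3 irradiated arrays all lay on 1 side of the 3 shams, leaving out provisional names. It adds the 4 members of each list with the smallest p, the 5 smallest p per direction for slopes and time differences, and at every dose Cdkn1a, Mdm2, Bax, Ccng1, Phlda3, Trp53inp1, Aen, Eda2r, Cd79a, Ms4a1, Cd3e, Ncr1, S100a8, Csf1r, Alas2 and Pf4. Some genes that the rule takes are not reported here. The 24 lists, of 672 genes, were p53 targets, double-strand break repair, apoptosis, B cell, T cell, NK and cytotoxic cell, neutrophil, granule precursor, monocyte, erythroid, platelet, eosinophil with basophil and mast cell, dendritic cell, MHC class II, proliferation, progenitor, interferon, inflammatory, oxidative stress, immediate-early, circadian clock, glucocorticoid, long noncoding RNA and ribosomal protein genes. After the data were seen, 10 tissue lists were added. Their means were taken after values below a floor were set at it, the floor being the highest, over the arrays compared, of the lowest signal among probes well above background.

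Alternatives were quantile normalization, no filter on dim probes, only genes well above background on all arrays of a compared group, only the compared groups in the fit, the replicate number as a block, the slide as a block, array weights, eBayes with trend and robust options, the mean of probes, the authors' scaled values, dose as log2 of Gy plus 1, and leaving out each array. Added after the data were seen were normexp background correction (offset 50) on the median signal, setting aside 3 arrays that stood apart, and tissue marker means as covariates, as well as the list tests with the slide as a block and over genes above background on all arrays. Arrays lay on 8 slides, given by the file headers. At 24 hr each slide held every dose, all 6 hr arrays shared a slide, and the 48 hr 8 Gy arrays shared none with the shams. Where a slide held both groups the comparison was also made within it, from group-by-slide means fitted over all arrays of a version. The test was run on uncorrelated simulated genes, 100 changed 2-fold and 100 4-fold. A shifted list was found, with 0 of 23 others called.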

Results

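Gene expression was measured in whole blood of female C57BL/6 mice, 6 to 8 weeks old, after whole-body irradiation or sham treatment. The labels give both gamma rays and X-rays as the source, a conflict not settled here. The series asks how expression in 16 groups of 3 mice changes with dose and time. Values are relative to each array's scale, so changes need not be changes in cell number. Doses were 0 and 4 Gy at 6 hr and 0, 1, 2, 4, 8 and 12 Gy at 16 hr. At 24 and 48 hr, on another design, they were 0, 2, 4 and 8 Gy. Between 13.9% and 48.4% of probes were well above background on the 24 and 48 hr arrays, and between 17.4% and 65.1% on the 6 and 16 hr arrays. Precision is limited: 3 arrays against 3 cannot go below an exact p of 0.1. Values in parentheses after a gene are log2 changes, irradiated minus sham of the same time, ± the standard error (n = 3 per group). A list's value is the median log2 change of its measured members. A gene not well above background on any array of a group has only a bound, given as "at least".

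At 6 hr after 4 Gy, transcripts of B cells were far lower and transcripts of neutrophils higher than in sham-irradiated mice. Of the B cell markers, 24 of 27 fell (24 adjusted over the list alone), with a median of -4.95 (adjusted p = 1.22e-26, and adjusted p = 0.0647 with an estimated correlation). They included Vpreb3 (-6.32 ± 0.50), Cd79b (-5.72 ± 0.95), Ms4a1 (-5.70 ± 1.00) and Cd72 (-5.72 ± 0.50), components or partners of the B cell receptor and surface proteins of B cells, at adjusted p from 5.54e-07 to 0.0022. Tnfrsf13c, the BAFF receptor (-6.41 ± 0.69, adjusted p = 3.77e-05), Fcrla (-6.04) and Chst3 (-5.52) were also among the 10 largest falls. MHC class II genes, which present antigen, fell with them, 10 of 11 and 11 adjusted over the list alone, with a median of -4.51 (adjusted p = 2.76e-11, and adjusted p = 0.337 with an estimated correlation). H2-DMb2 fell most (-6.65 ± 1.01, adjusted p = 0.000654), and H2-Eb2 was at least 12.6-fold lower. Of the genes named here, H2-DMb2, Tnfrsf13c, Fcrla, Cd72, Trat1 and Themis were well above background on 1 of 3 irradiated arrays and Vpreb3, Chst3 and Lef1 on 2 of 3. T cell markers had a median of -2.05 and 5 of 29 fell (11 adjusted over the list alone), among them Trat1 (-2.84 ± 0.46), Themis (-2.72 ± 0.55) and Lef1 (-2.82 ± 0.75). NK and cytotoxic cell markers had a median of -1.68 and 7 of 20 fell (14 adjusted over the list alone), with Klrd1 (-2.50 ± 0.57) and Gzma (-2.14 ± 0.55) among them. The set tests of these T and NK lists gave adjusted p from 3.98e-06 to 0.000356, and from 0.486 to 0.638 with an estimated correlation.

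Neutrophil markers rose at 6 hr: 18 of 24 rose (22 adjusted over the list alone), with a median of 2.75 (adjusted p = 7.78e-44, and adjusted p = 0.0596 with an estimated correlation). The members with the smallest p included Lrg1 (5.93 ± 0.70), Il1r2 (4.75 ± 0.69), Mmp8 (3.69 ± 0.53) and Fpr2 (3.38 ± 0.50), where Il1r2 is a decoy receptor for interleukin-1 and Mmp8 a neutrophil collagenase. Inflammatory and NF-kB genes shifted up as well (median 0.69; 7 of 24 rose, 8 adjusted over the list alone), with Socs3 (4.05 ± 0.69), Il1b (3.23 ± 0.60), Il1rn (3.32 ± 0.65) and Tlr2 (2.93 ± 0.55) at adjusted p from 0.00179 to 0.00513. Acod1, the enzyme that makes itaconate (4.99 ± 0.78, adjusted p = 0.000911), Prok2 (at least 7.48-fold higher, with 2 of 3 irradiated arrays well above background), Ier3 (4.62) and Ccdc80 (4.46) were among the 10 largest rises. Acod1, Ier3, Ccdc80 and Psrc1 were well above background on 1 of 3 shams. Of the p53 target genes, 3 rose and 1 fell of 36 (list median 0.38): Cdkn1a (3.71 ± 0.79), Psrc1 (3.26 ± 0.88) and Phlda3 (2.02 ± 0.47) rose, and Sesn1 fell (-2.97 ± 0.54, adjusted p = 0.00274). Cdkn1a encodes the cell cycle inhibitor p21. The glucocorticoid-responsive list (median 0.30) held a rise of Cebpd (2.85 ± 0.54) and Dusp1 (2.25 ± 0.61) and a fall of Cxcr4 (-2.43 ± 0.53). The oxidative stress and NRF2 list had a median of 0.23 (adjusted p = 5.63e-05, and adjusted p = 0.0382 with an estimated correlation). Of its 23 members 1 passed, glutathione reductase or Gsr (1.64 ± 0.38, adjusted p = 0.0168). Set tests also placed up the lists of platelet (0.89), monocyte (0.45), interferon (0.14), progenitor (0.32) and immediate-early genes (0.07), with 0 platelet, interferon or progenitor genes rising on their own. The p53, inflammatory, glucocorticoid, platelet, monocyte, interferon, progenitor and immediate-early calls had adjusted p from 1.14e-14 to 0.0154, and from 0.349 to 0.694 with an estimated correlation. Ribosomal protein genes (median -1.02; 2 of 35 fell, 19 adjusted over the list alone) and double-strand break repair genes (median -0.89; 0 of 26 fell, 6 adjusted over the list alone) shifted down, at adjusted p from 5.63e-05 to 0.0293, and from 0.545 to 0.554 with an estimated correlation. The granule precursor list was called up although its median was -0.23 and its mean -0.18, and the erythroid list was called up with a median of 0.04 and a mean of -0.06. These 2 set tests had adjusted p from 0.00982 to 0.0296, and from 0.694 to 0.815 with an estimated correlation. Leaving out 1 array ended the calls of double-strand break repair genes without 4 Gy replicate 1, erythroid genes without 4 Gy replicate 2, and granule precursor genes without sham replicate 1 or 4 Gy replicate 3. The repair call was also lost with quantile normalization, the erythroid and progenitor calls with it, and the granule call with scaling over all probes.

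In all, 186 genes rose and 1058 fell of 21932 tested at 6 hr (limma, adjusted p under 0.05), and 1235 of these 1244 were well above background on all arrays of a compared group. All 4 Gy arrays were dimmer than every sham, with 28.9% to 44.0% of probes well above background against 47.7% to 65.1%. The median over all genes was -0.40. With quantile normalization 255 and 283 genes rose and fell (median of all genes 0.08), and with scaling over all probes 581 and 545 (median 0.26), so the balance of rises and falls changed with the scaling. With slide as a block 453 and 4380 genes rose and fell, and within the slide that held all 6 hr arrays 465 and 4220 did. The count of 1244 was 430, 405 and 459 without sham replicates 1, 2 and 3 and 692 and 467 without 4 Gy replicates 1 and 2.

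At 16 hr after 8 Gy both B and T cell transcripts were lower and platelet transcripts higher than in shams. Of the B cell markers, 22 of 27 fell (23 adjusted over the list alone), with a median of -4.59 (adjusted p = 6.64e-19, and adjusted p = 0.136 with an estimated correlation). With genes that had only a bound set at that bound, the median was -2.90. The largest falls included Cd79b (-6.41 ± 0.95), Ms4a1 (-6.03 ± 1.00), Ly6d (-5.93 ± 0.87) and Pou2af1 (-5.49) at adjusted p from 0.00188 to 0.00666. Fcer2a, the low-affinity IgE receptor, was at least 13.7-fold lower and Cxcr5, the chemokine receptor of follicular lymphocytes, at least 13.5-fold lower. T cell markers had a median of -3.33 and 19 of 29 fell (26 adjusted over the list alone), with Cd8b1 (-5.25 ± 0.85) and Ccr7 (-4.79 ± 1.00), and Thy1 was at least 34.4-fold lower. Of these, Cd79b, Ms4a1, Pou2af1 and Ccr7 were well above background on 1 of 3 irradiated arrays and Cd8b1 on 2 of 3. All 11 MHC class II genes fell (median -4.61), and so did 21 of 35 ribosomal protein genes (median -1.45), among them Rps18 (-3.40 ± 0.70) and Rpl22 (-2.50 ± 0.52). With bounds set in the same way, the T cell and MHC class II medians were -2.27 and -4.35. The T cell, MHC class II and ribosomal set tests gave adjusted p from 1.62e-12 to 3.3e-09, and from 0.349 to 0.426 with an estimated correlation.

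Platelet and megakaryocyte markers rose at 16 hr after 8 Gy, 27 of 27 over all genes and as many adjusted over the list alone, with a median of 2.19 (adjusted p = 4.31e-25, and adjusted p = 0.335 with an estimated correlation). They included Thbs1 (2.85 ± 0.45), Gp1ba (2.68 ± 0.51), Tubb1 (2.86 ± 0.55) and Plek (2.11 ± 0.41), which encode thrombospondin 1, a subunit of the von Willebrand factor receptor, the tubulin of platelets and pleckstrin. Slfn4, a Schlafen family gene of myeloid cells (3.93 ± 0.76, adjusted p = 0.00612), the interferon-inducible Ifitm1 (3.64 ± 0.54, adjusted p = 0.00191), Cdkn1a (3.52 ± 0.79, adjusted p = 0.00912) and Tspan9 (3.34) were among the 10 largest rises, with Mtss2 (at least 7.37-fold higher). Nrcam was among them too, but with 1 of 3 irradiated arrays and 0 shams well above background. Cdkn1a, Tspan9 and Meis1 were well above background on 1 of 3 shams, and Slfn4 and Epor on 2 of 3. Interferon-stimulated genes had a median of 0.36 and 5 of 34 rose (5 adjusted over the list alone), Igtp (2.01 ± 0.39) and Ifit2 (2.01 ± 0.42) among them. Neutrophil markers had a median of 0.85 (4 of 24 rose, 4 adjusted over the list alone), and haematopoietic progenitor markers a median of 0.29 (5 of 14 rose, 5 adjusted over the list alone), with Gata2 (2.50 ± 0.45) and Meis1 (1.89 ± 0.41). The interferon, neutrophil and progenitor set tests had adjusted p from 2.31e-06 to 0.0111, and from 0.349 to 0.65 with an estimated correlation, and the progenitor call was lost with slide as a block. The erythroid list was called up with a median of -0.07 and a mean of 0.26 (adjusted p = 0.0268, and adjusted p = 0.805 with an estimated correlation). That call was lost with quantile normalization and without sham replicates 2 or 3 or 8 Gy replicate 3, and its 4 named members rose, Epor (2.46 ± 0.44), Tal1 (2.73 ± 0.53), Gata1 (1.79 ± 0.44) and Sptb, not well above background on any sham.

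In all, 814 genes rose and 1955 fell at 16 hr after 8 Gy, 2455 of these 2769 well above background on all arrays of a compared group, with a median of -0.15 over all genes. All 8 Gy arrays were dimmer than every sham (18.7% to 21.9% of probes well above background against 24.0% to 37.1%). Scaling over all probes gave 1156 and 1464 (median 0.30). With slide as a block 1422 and 4604 rose and fell, and within the slides that held both groups 328 and 992, and 300 and 836, from 1 irradiated array against 2 shams and 1 against 1, a lone array being assumed to vary like the rest. The B cell median was -4.09 and -5.06 within those slides, and the platelet median 1.91 and 2.76. The count was 1718 and 199 without sham replicates 2 and 3 and 953 and 796 without 8 Gy replicates 1 and 2.

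At 16 hr after 1 Gy 0 genes passed (limma; 1611 genes had an unadjusted p under 0.05, where chance gives 1097), and leaving out sham replicate 2 gave 3. At 2 Gy 0 genes rose and 1 fell (1898 at an unadjusted p under 0.05); the 1 gene has a transcript identifier and no symbol in the files (log2 change -3.14 ± 0.43, adjusted p = 0.00956), and was looked up after its value was seen. That count of 1 was 0 without sham replicate 2 and 22, 0 and 3 without 2 Gy replicates 1, 2 and 3. At 4 Gy 64 rose and 31 fell, and the count of 95 was 32 and 7 without sham replicates 2 and 3 and 14 and 9 without 4 Gy replicates 1 and 2. At 12 Gy 61 rose and 128 fell, and the count of 189 was 63 and 52 without sham replicates 2 and 3 and 114, 311 and 62 without 12 Gy replicates 1, 2 and 3. With slide as a block, 259 and 38 genes rose and fell at 1 Gy, 0 and 0 at 2 Gy, 386 and 81 at 4 Gy and 70 and 639 at 12 Gy. Within single slides, with 1 or 2 arrays of a group, the counts were 0 and 34 at 1 Gy, 1 at 2 Gy, 96 at 4 Gy and 639 at 12 Gy. The medians over all genes were -0.17, -0.24, -0.29 and -0.11 at 1, 2, 4 and 12 Gy. With quantile normalization they were -0.12, 0.06, 0.01 and -0.05, with 5 and 5 genes up and down at 2 Gy, 27 and 13 at 4 Gy and 152 and 275 at 12 Gy.

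By list, platelet markers were placed up at every dose at 16 hr, with medians of 1.71, 1.16, 1.64 and 1.52 at 1, 2, 4 and 12 Gy, and 25, 6, 26 and 27 of 27 members rose adjusted over the list alone. T cell markers were placed down at these doses (medians -1.05, -1.33, -2.29 and -2.01), and interferon-stimulated genes up (medians 0.21, 0.50, 1.05 and 1.21). The estimated-correlation adjusted p of these 12 calls lay between 0.189 and 0.795. B cell markers were not called at 1 Gy (median -0.34). They had medians of -1.77 at 2 Gy and -1.24 at 4 Gy, -0.92 and -0.61 with slide as a block, and -1.36 and -0.39 within a slide. At 12 Gy the B cell median was -4.15, 18 of 27 fell (24 adjusted over the list alone), and the call held with an estimated correlation (adjusted p = 0.0382). MHC class II genes were placed down at 2, 4 and 12 Gy (medians -1.90, -1.42 and -3.20), and the 4 Gy call was lost without 4 Gy replicate 1. At 1 Gy serous cavity macrophage markers lay -1.61 from the shams, with 3 of 3 arrays below all shams. At 2 and 4 Gy they lay 1.40 and 1.27 above, cardiac markers 1.47 above at 2 Gy and airway and B-1 cell markers 2.41 and 0.28 above at 4 Gy, each with 2 of 3 arrays above all shams, and B-2 cell markers -2.16 and -2.63 from the shams, with 3 of 3 below. Neutrophil markers were placed up at 1, 2, 4 and 12 Gy (medians 0.39, 1.03, 0.62 and 0.81, and -0.11 within a slide at 12 Gy). The 2, 4 and 12 Gy B cell and MHC class II calls and the neutrophil calls had estimated-correlation adjusted p from 0.0382 to 0.694. On the 12 Gy replicate 2 array the T cell marker mean lay 2.66 above the other 2 arrays of its group and the thymocyte marker mean 1.57 above them, while its B cell mean lay -0.03 from theirs. The T cell median at 12 Gy within the slide shared with shams was -2.87.

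Other lists called at 2, 4 or 12 Gy at 16 hr, with their median log2 changes, whose sign is the direction called, were NK and cytotoxic cell genes (0.33 at 4 Gy, -1.09 at 12 Gy), monocyte genes (0.13 at 2 Gy, 0.39 at 4 Gy, 0.35 at 12 Gy) and erythroid genes (-0.48 at 2 Gy, -0.62 at 4 Gy). Also called were inflammatory genes (0.39 at 4 Gy, 0.48 at 12 Gy), p53 target genes (0.03 at 2 Gy, 0.38 at 4 Gy, 0.74 at 12 Gy) and apoptosis genes (0.30 at 4 Gy). Calls were made too for ribosomal protein genes (-0.39 at 2 Gy, -0.44 at 4 Gy, -0.87 at 12 Gy), haematopoietic progenitor genes (0.19 at 2 Gy, 0.46 at 4 Gy, 0.67 at 12 Gy) and immediate-early genes (0.42 at 4 Gy). Further calls were those of glucocorticoid-responsive genes (0.80 at 4 Gy) and proliferation genes (-0.53 at 2 Gy, -0.75 at 4 Gy, 0.36 at 12 Gy). Their adjusted p lay from 1.64e-08 to 0.0458, and from 0.337 to 0.795 with an estimated correlation. Of the p53 target genes 3 rose at 4 Gy and 4 at 12 Gy. Serous cavity macrophage markers lay 2.59 and further such markers 1.12 above the shams at 12 Gy, with 3 of 3 arrays above all shams. At 2 Gy the p53, monocyte, erythroid, proliferation, progenitor and ribosomal calls were each lost without 2 Gy replicate 3, and all but the p53 call without 2 Gy replicate 2. They were also lost without sham replicate 1 (p53, erythroid and proliferation), 2 (p53, monocyte and ribosomal) or 3 (progenitor and ribosomal). At 1 Gy the neutrophil and interferon calls were lost without 1 Gy replicate 3, and the interferon call without sham replicate 2. At 4 Gy calls were lost without sham replicate 1 (erythroid), 2 (ribosomal) or 3 (NK), and without 4 Gy replicate 1 (NK and ribosomal), 2 (erythroid) or 3 (immediate-early). At 12 Gy the monocyte, inflammatory, progenitor and proliferation calls were lost without 12 Gy replicate 2, and calls were lost without 12 Gy replicate 3 (monocyte) and sham replicates 1 (inflammatory), 2 (inflammatory and proliferation) and 3 (proliferation). At 12 Gy the NK, monocyte, proliferation, progenitor and inflammatory calls were lost with slide as a block.

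Across all doses at 16 hr, 4 of the 5 genes with the clearest fall per Gy were B cell markers. They were Vpreb3, Fcmr, Fcer2a, Tnfrsf13c and Dapl1, at adjusted p from 1.24e-07 to 7.49e-06. Fcmr had a slope of -0.53 ± 0.04 log2 per Gy. The other falling genes were not well above background on any array of 2 groups, so the size of their slopes is not fixed. The clearest rises were Crip2 (0.18 ± 0.03), Slfn4 (0.30 ± 0.05) and Cpped1 (0.12 ± 0.02), with Tmem86a and Mtss2, which were not well above background on any sham, at adjusted p from 0.000665 to 0.00288. In all 107 genes had a rising and 437 a falling slope, 325 and 1070 with quantile normalization and 205 and 1950 with slide as a block. The count of 544 was 286 and 241 without sham replicates 2 and 3, 275 and 285 without 1 Gy replicates 2 and 3, 1474 without 2 Gy replicate 1, 1034 without 4 Gy replicate 1, 317 and 310 without 8 Gy replicates 1 and 2 and 214, 1125 and 166 without 12 Gy replicates 1, 2 and 3.

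At 24 hr after 8 Gy, T cell and B cell transcripts were lower and transcripts of neutrophils and of the interferon response higher. Of the T cell markers, 21 of 29 fell (24 adjusted over the list alone), with a median of -3.17 (adjusted p = 8.68e-30, and adjusted p = 0.0865 with an estimated correlation). Ccr7, which guides T cells to lymph nodes (-4.67 ± 0.49, adjusted p = 1.87e-05), Cd3d, a chain of the T cell receptor complex (-4.44 ± 0.48, adjusted p = 1.87e-05), and Ets1 (-4.63 ± 0.64), Thy1 (-4.49 ± 0.54) and Tcf7 (-4.18 ± 0.49) fell. Of the B cell markers, 19 of 25 fell (24 adjusted over the list alone), with a median of -3.53 (adjusted p = 7.83e-28, and adjusted p = 0.0928 with an estimated correlation), and Vpreb3 fell by the largest amount measured on both sides (-5.57 ± 0.47, adjusted p = 2.2e-06). Fcer2a was at least 22.6-fold lower and Dapl1 at least 11.6-fold lower. Vpreb3, Ets1, Cd3d and Tcf7, and H2-DMb2 and H2-Oa named next, were well above background on 1 of 3 irradiated arrays, and Ccr7 and Thy1 on 2 of 3. MHC class II genes had a median of -3.78 (6 of 10 fell, 10 adjusted over the list alone), with H2-DMb2 (-4.65 ± 1.13) and H2-Oa (-4.61 ± 0.80), at adjusted p = 0.349 with an estimated correlation. On the replicate 3 array of this group the mean of serous cavity macrophage markers lay 5.35 above the other 2 arrays, the B-1 cell mean 0.89 above and the B cell mean 1.18 above. The B cell median was -4.72 within the slide that held replicates 1 and 2 and -1.45 within the slide that held replicate 3, and the MHC class II medians were -5.17 and -0.94.

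Among genes that rose at 24 hr after 8 Gy, Slfn4 (5.29 ± 0.69, adjusted p = 0.000127, 2 of 3 shams well above background), Ifitm1 (3.98 ± 0.46, adjusted p = 4.32e-05), Lrg1 (3.69), Wfdc17 (3.42) and Ifit3b (3.41) were among the 10 largest. Cdkn1a was at least 25.9-fold higher, the growth factor binding protein Igfbp6 at least 10.3-fold higher and cyclin D1 (Ccnd1) at least 9.74-fold higher. Interferon-stimulated genes had a median of 1.23 and 7 of 34 rose (15 adjusted over the list alone), with Ifit3 (3.31 ± 0.50), Oas2 (2.77 ± 0.58) and Oasl1 (2.23 ± 0.42), genes of the antiviral response. Neutrophil markers had a median of 1.87 and 13 of 25 rose (20 adjusted over the list alone), with Hdc (2.40 ± 0.43) and Clec4d (1.81 ± 0.30), and granule precursors a median of 0.91 (3 of 18 rose, 5 adjusted over the list alone). Of the p53 target genes 7 rose and 1 fell of 34 (median 0.65); Phlda3 (2.86 ± 0.37), an inhibitor of AKT signalling, rose and Dgka (-2.47 ± 0.46) fell. Platelet markers had a median of 1.25 and 3 of 27 rose (3 adjusted over the list alone), among them F5 (1.86 ± 0.34), Selp (2.45 ± 0.56) and Thbs1 (1.78 ± 0.44); the median was 1.74 and 0.20 within the slides. The interferon, neutrophil, granule, p53 and platelet set tests had adjusted p from 7.53e-17 to 0.009, and from 0.0647 to 0.577 with an estimated correlation. NK (median -0.95) and ribosomal protein genes (median -0.86) were placed down, at adjusted p from 4.82e-06 to 0.00184, and from 0.545 to 0.661 with an estimated correlation.

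In all, 284 genes rose and 364 fell at 24 hr after 8 Gy, 520 of these 648 well above background on all arrays of a compared group. At 2 Gy 466 rose and 825 fell, and at 4 Gy 880 and 1123. All 2 and 4 Gy arrays were dimmer than every sham (17.4% to 27.3% of probes well above background against 28.6% to 30.7%), and 8 Gy arrays ranged from 13.9% to 37.7%. The medians over all genes were -0.29, -0.03 and 0.05 at 2, 4 and 8 Gy, -0.07, -0.15 and -0.10 with quantile normalization and 0.18, -0.01 and -0.04 with scaling over all probes. The splits moved with the scaling: quantile normalization gave 814 and 701 at 2 Gy, 1294 and 1930 at 4 Gy and 586 and 1378 at 8 Gy, and scaling over all probes 776 and 337, 679 and 1612 and 287 and 729. With slide as a block 700 and 1188, 1146 and 1451 and 426 and 502 rose and fell. Within the slide with 2 arrays of each group the splits were 84 and 341, 528 and 723, and 773 and 2046, and within the slide with 1 array of each they were 0 and 0, 0 and 0, and 180 and 79, where a lone array is assumed to vary like the rest. The 2 Gy count of 1291 was 50 and 101 without sham replicates 1 and 2 and 125, 241 and 165 without 2 Gy replicates 1, 2 and 3. The 4 Gy count of 2003 was 318, 447 and 1125 without sham replicates 1, 2 and 3 and 206, 827 and 1146 without 4 Gy replicates 1, 2 and 3. The 8 Gy count of 648 was 202, 273 and 400 without sham replicates 1, 2 and 3 and 271, 344 and 3631 without 8 Gy replicates 1, 2 and 3.

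At 2 and 4 Gy at 24 hr, B cell, T cell and MHC class II lists were placed down and neutrophil, platelet and interferon lists up. B cell markers had medians of -2.37 and -3.16, with 12 and 20 of 25 members falling, T cell markers -1.87 and -2.34 (15 and 20 of 29), and MHC class II genes -2.69 and -3.42 (2 and 7 of 10). Neutrophil markers had medians of 1.68 and 1.63 (11 and 13 of 25 rose), platelet markers 1.75 and 1.98 (12 and 21 of 27) and interferon-stimulated genes 0.74 and 0.74 (5 and 7). These 12 calls had adjusted p from 0.0647 to 0.575 with an estimated correlation. At 4 Gy airway and cardiac markers lay 1.34 and 0.89 above the shams, with 2 of 3 arrays above all shams. At 8 Gy cardiac markers lay 0.24 above, with 3 of 3. Other called lists, by median and its sign, were granule precursor genes (0.59 at 2 Gy), double-strand break repair genes (-1.02 at 2 Gy, -0.93 at 4 Gy) and ribosomal protein genes (-0.84 at 2 Gy, -1.11 at 4 Gy). Also called were haematopoietic progenitor genes (0.48 at 2 Gy, 0.97 at 4 Gy) and eosinophil, basophil and mast cell genes (0.37 at 2 Gy). Their adjusted p lay from 2.31e-06 to 0.0293, and from 0.364 to 0.781 with an estimated correlation. At 8 Gy the NK, granule and p53 calls were lost without 8 Gy replicate 3, alone or with 2 arrays of other groups. At 4 Gy the repair call was lost without 4 Gy replicate 3 and the progenitor call without 4 Gy replicate 2. At 2 Gy the eosinophil and ribosomal calls were lost without 2 Gy replicate 1, and the progenitor and ribosomal calls without sham replicate 3. The linear slope with dose passed for 191 rising and 216 falling genes, 383 and 1136 with quantile normalization, 146 and 562 with scaling over all probes and 282 and 267 with slide as a block. The clearest rises per Gy were Ifitm1 (0.40 ± 0.06), Slfn4 (0.57 ± 0.08), Phlda3 (0.30 ± 0.04) and Igfbp6. The clearest falls were Vpreb3 (-0.69 ± 0.06), Dusp2 (-0.55 ± 0.06), Cd3d (-0.54 ± 0.06), Ccr7 (-0.54 ± 0.06) and Fcer2a. Igfbp6 was not well above background on any sham nor Fcer2a on any 8 Gy array, so no size is given for them, and these 9 genes had adjusted p from 1.31e-06 to 0.000588. The count of 407 slopes was 159, 213 and 202 without sham replicates 1, 2 and 3, 250 without 2 Gy replicate 2 and 150, 163 and 2619 without 8 Gy replicates 1, 2 and 3.

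At 48 hr after 8 Gy, red cell precursor transcripts were lower as well as those of B and T cells, and platelet, neutrophil and p53 target genes were higher. Of the erythroid markers 6 rose and 21 fell of 37 (median -2.02), with falls of Slc25a37 (-3.57 ± 0.62), Hemgn (-3.30 ± 0.55) and Car1 (-2.91 ± 0.50), where Slc25a37 is the mitochondrial iron importer mitoferrin and Car1 a carbonic anhydrase of red cells. Epor, the erythropoietin receptor, rose (3.62 ± 0.61, adjusted p = 0.000155). Of the B cell markers 1 rose and 24 fell of 25 (median -3.92), and of the T cell markers 1 rose and 24 fell of 29 (median -2.32), with Vpreb3 (-7.26 ± 0.47), Ccr6 (-6.03 ± 0.79), Fcer2a (-6.01 ± 0.62), Cd8a (-4.42 ± 0.60) and Ccr7 (-3.98 ± 0.49) at adjusted p from 1.56e-08 to 2.52e-05. Ccr6, Fcer2a and Kmo were well above background on 1 of 3 irradiated arrays and Cd8a on 2 of 3. All 10 MHC class II genes (median -3.76) and 34 of 35 ribosomal protein genes (median -1.98) fell. Chil3, a chitinase-like protein of myeloid cells (-6.37 ± 0.77, adjusted p = 1.13e-05), Kmo, an enzyme of kynurenine metabolism (-5.54), and Nusap1, a spindle protein (-5.33), were also among the 10 largest falls. The erythroid, B cell, T cell, MHC class II and ribosomal set tests had adjusted p from 2.31e-09 to 0.0296, and from 0.422 to 0.838 with an estimated correlation. With slide as a block their medians were -2.88, -2.64, -1.94, -2.71 and -1.64.

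Platelet markers rose at 48 hr after 8 Gy (24 of 27 rose, 24 adjusted over the list alone; median 2.91, 2.17 with slide as a block), including Selp (4.43 ± 0.56), Gp1ba (4.09 ± 0.60), Thbs1 (3.54 ± 0.44) and F5 (3.40 ± 0.34). Neutrophil markers had a median of 2.11 (15 rose and 2 fell of 25), with Lrg1 (4.38 ± 0.68), Asprv1 (3.02 ± 0.45) and Clec4d (2.45 ± 0.30). Of the p53 target genes 14 rose and 4 fell of 34 (median 0.93): Phlda3 (4.16 ± 0.37, adjusted p = 1.4e-06) and Bbc3 (3.02 ± 0.42, adjusted p = 2.93e-05) rose, Bbc3 being the pro-apoptotic protein PUMA, and Cdkn1a was at least 11.7-fold higher. Apoptosis regulators had a median of 0.73 (9 rose and 3 fell of 23), with Xiap (1.92 ± 0.31) and Bid (2.63 ± 0.47), and glucocorticoid-responsive genes 0.92 (5 of 17 rose, 5 adjusted over the list alone), with Gadd45g (2.83 ± 0.48). The platelet, neutrophil, p53, apoptosis and glucocorticoid set tests had adjusted p from 1.49e-14 to 0.0273, and from 0.335 to 0.645 with an estimated correlation. The 10 largest rises held Actn1 (5.25 ± 0.80), Tpm2 (5.25 ± 0.62) and Cnn1 (at least 20.9-fold higher), with Clip2 (at least 14.6-fold higher), Proser2 (4.93) and the endothelial gene Plvap (at least 25.7-fold higher). Actn1 was well above background on 1 of 3 shams, and Lrg1 and Selp on 2 of 3. Cardiac muscle and serous cavity macrophage markers also lay higher, by a mean of 1.90 and 2.31, with 1 and 2 of 3 arrays above all shams.

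In all, 3146 genes rose and 5502 fell at 48 hr after 8 Gy, 7559 of these 8648 well above background on all arrays of a compared group. At 2 Gy 1493 rose and 1297 fell, and at 4 Gy 3118 and 4266. All irradiated arrays were brighter than every sham (35.4% to 48.4% of probes well above background against 27.0% to 31.4%). The medians over all genes were -0.39, -0.02 and -0.54. With quantile normalization the medians were 0.00, 0.19 and 0.02 and the splits 1483 and 496, 3257 and 2547 and 3867 and 2676, and with scaling over all probes the medians were 0.00, 0.17 and 0.05 and the splits 2090 and 507, 3823 and 3596 and 4491 and 2847. The 8 Gy arrays shared no slide with the shams; with slide as a block the splits were 1265 and 1176, 3136 and 4061 and 1936 and 2784, and within the slide that held the shams 1160 and 962 at 2 Gy and 3441 and 3902 at 4 Gy. The 2 Gy count of 2790 was 1266, 1465 and 1339 without sham replicates 1, 2 and 3 and 1136 and 924 without 2 Gy replicates 2 and 3.

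At 2 and 4 Gy at 48 hr, erythroid markers had medians of -1.70 and -2.73 (16 and 25 of 37 fell), B cell markers -2.15 and -2.29 (12 and 17 of 25) and MHC class II genes -1.98 and -2.46 (2 and 5 of 10). Platelet markers had medians of 2.00 and 2.08 (20 and 18 of 27 rose), neutrophil markers 1.19 and 1.71 (9 and 16 of 25) and p53 target genes 0.27 and 1.07 (4 and 14 of 34). These 12 calls had adjusted p from 0.349 to 0.795 with an estimated correlation. Other called lists, by median and its sign, were T cell genes (-1.71 at 4 Gy), NK and cytotoxic cell genes (0.71 at 2 Gy) and inflammatory genes (0.72 at 4 Gy). Also called were apoptosis genes (0.20 at 2 Gy, 0.97 at 4 Gy), ribosomal protein genes (-0.90 at 2 Gy, -1.30 at 4 Gy) and haematopoietic progenitor genes (0.75 at 2 Gy). Calls were made too for immediate-early genes (1.08 at 4 Gy), glucocorticoid-responsive genes (1.09 at 2 Gy, 1.69 at 4 Gy) and long noncoding RNA genes (0.22 at 4 Gy). Their adjusted p lay from 7.73e-08 to 0.0446, and from 0.408 to 0.75 with an estimated correlation. At 2 Gy calls were lost without replicate 1 (NK) and without replicate 2 or sham replicates 1 or 2 (progenitor). At 4 Gy calls were lost without replicate 1 (immediate-early, inflammatory, noncoding RNA), replicate 2 (immediate-early) or sham replicate 3 (immediate-early, noncoding RNA). The B cell mean of 4 Gy replicate 1 lay 2.36 above its group's other arrays (no floor). At 8 Gy the erythroid call was lost without replicate 1 or sham replicate 3. The T cell list was not called at 2 Gy (median -0.36). Serous cavity macrophage markers lay 3.13 and 4.55 above the shams at 2 and 4 Gy, with 3 of 3 arrays above all shams. Cardiac markers lay 2.53 and 2.18 above, with 3 and 2 of 3. Chance parts 3 arrays from 3 fully in 10% of cases. The linear slope with dose passed for 3088 rising and 5094 falling genes, 3630 and 2485 with quantile normalization, 4379 and 2889 with scaling over all probes and 1736 and 2587 with slide as a block. The clearest rises per Gy were Phlda3 (0.47 ± 0.04), Nav1 (0.49 ± 0.05), Lgals3bp (0.47 ± 0.05), F5 (0.38 ± 0.04) and Mgmt (0.42 ± 0.05). The clearest falls were Vpreb3 (-0.88 ± 0.06), Kmo (-0.70 ± 0.06), Cdc25b (-0.57 ± 0.05), Dapl1 (-0.81 ± 0.08) and Fcer2a (-0.72 ± 0.07), and these 10 genes had adjusted p from 1.11e-08 to 1.11e-05.

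The effect of irradiation differed between 48 and 24 hr for more genes with a lower than with a higher effect at 48 hr, a balance that turned when scaling over all probes. Over 2, 4 and 8 Gy together, the log2 changes at 24 and at 48 hr were Lig1 (-0.19 and -3.84), Cdc25b (-1.08 and -4.30), Ogfod1 (-1.51 and -4.33), Ralgps1 (-1.14 and -3.97) and Pstpip2 (0.51 and -2.41) among the clearest downward differences. Lig1 is the replicative DNA ligase and Cdc25b a phosphatase that starts mitosis. The clearest upward differences were Chd4 (-0.69 and 2.01), Lpp (0.01 and 2.72), Terf2 (-0.75 and 2.19), Ppfibp1 and Pdk2. Ppfibp1 and Pdk2 were not well above background on any array of 4 and 3 groups, the 48 hr shams among them, and with normexp background correction their differences turned to -0.24 and -0.23. These 10 genes had adjusted p from 0.0103 to 0.0111. Alas2, the first enzyme of haem synthesis in red cell precursors, had changes of -0.01 and -2.46 (difference -2.46 ± 0.74, adjusted p = 0.0324). In all 641 genes had a higher and 2165 a lower effect at 48 hr, 601 and 765 with quantile normalization, 623 and 309 with scaling over all probes and 537 and 2248 with slide as a block. The median over all genes was 0.15, 0.49 and 0.41 under the main, quantile and all-probe scalings. The count of 2806 was 244 and 95 without 24 hr sham replicates 1 and 2, 4847 without 24 hr 8 Gy replicate 3 and 1578, 1620 and 0 without 48 hr sham replicates 1, 2 and 3. The 24 and 48 hr arrays lay on separate slides, so slide and time cannot be told apart there beyond what the shams of each time remove. At 4 Gy 0 genes differed in their effect between 16 and 6 hr (limma; 1009 genes had an unadjusted p under 0.05, where chance gives 1097). With slide as a block 291 and 11 genes differed, and the count of 0 was 6 without 6 hr 4 Gy replicate 2 and 191 without 16 hr 4 Gy replicate 1.

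Overlap between comparisons with separate shams varied, with r across genes from -0.005 (16 hr 1 Gy and 48 hr 4 Gy) to 0.767 (16 hr 8 Gy and 24 hr 4 Gy). For 4 Gy at 6 and 24 hr, 67 genes rose at both (independent lists would share 8.4) and 191 fell at both (36.3), 1 moved in opposite directions, and r was 0.699. For 8 Gy at 16 and 24 hr, 88 genes rose at both (11.4) and 191 fell at both (30.1), 0 moved in opposite directions, and r was 0.674. For 8 Gy at 16 hr and 4 Gy at 48 hr, 551 rose at both (127) and 239 fell at both (304), 26 moved in opposite directions, and r was 0.105. Genes are not independent replicates, and the correlations describe these arrays only.

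**Figure D1:**
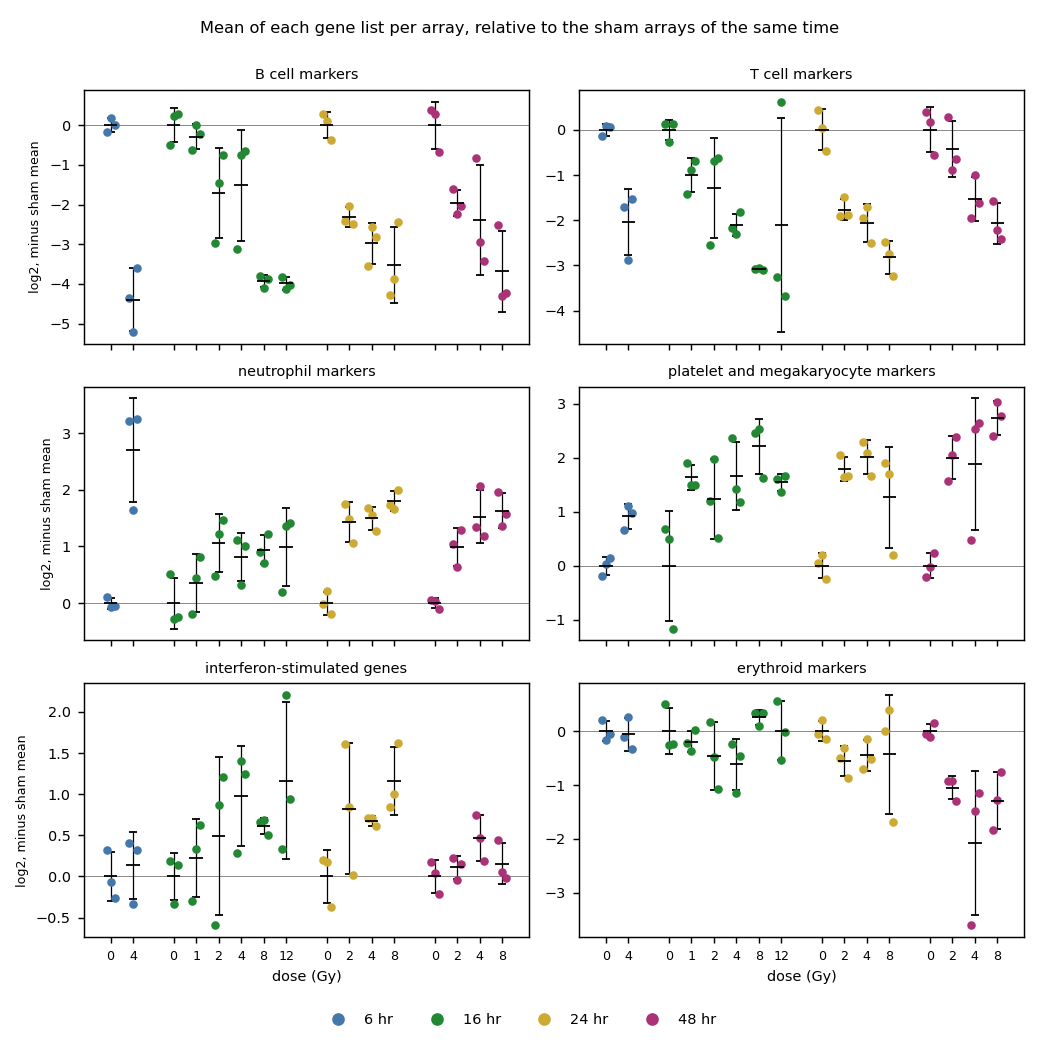
Mean log2 expression of 6 gene lists per array (points), centred on the sham mean of each time, against dose in Gy at 6, 16, 24 and 48 hr, with bars for the mean and SD of 3 mice. B cell markers lay below the shams at 8 Gy (list medians -4.59, -3.53 and -3.92 at 16, 24 and 48 hr), and platelet markers lay above the shams at these times (medians 2.19, 1.25 and 2.91). With genes at bounds the -4.59 was -2.90.

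Of the p53 target genes named at every dose and time, Cdkn1a and Phlda3 rose in 10 of the 12 comparisons with sham, all except 1 and 2 Gy at 16 hr. Cdkn1a was not well above background in the 24 and 48 hr shams, and was at least 7.25, 9.31 and 25.9-fold higher after 2, 4 and 8 Gy at 24 hr and at least 5.1, 20.5 and 11.7-fold higher at 48 hr. Ccng1, cyclin G1, rose in 7 comparisons, at 4 Gy and above from 16 hr on, by 1.67 to 2.43. Aen, an apoptosis-enhancing nuclease, rose at 24 hr after 8 Gy (2.20 ± 0.49, adjusted p = 0.0153) and at 48 hr after 4 and 8 Gy (1.96 and 1.80). Mdm2, the ubiquitin ligase that restrains p53, rose at 48 hr after 4 and 8 Gy (1.34 and 1.49), and Trp53inp1 at 48 hr after 8 Gy (1.41). Bax, a pro-apoptotic BCL-2 family member, passed only at 48 hr, where it fell at 4 Gy (-1.14 ± 0.44, adjusted p = 0.0431) and 8 Gy (-1.76 ± 0.44, adjusted p = 0.00296). Eda2r was not measured. Among the cell markers named throughout, Cd3e fell at 16 hr after 8 Gy (-3.45), at every dose at 24 hr (-1.73, -2.33 and -3.72) and at 48 hr after 4 and 8 Gy (-1.57 and -2.06). S100a8, a calcium-binding protein abundant in neutrophils, rose at 6 hr (2.42) and at 24 hr after 2 and 4 Gy (2.10 and 1.79), and Pf4, platelet factor 4, at 16 hr after 8 Gy (1.68) and at 24 hr after 2 and 4 Gy (1.71 and 1.71). Alas2 fell at 48 hr after 4 and 8 Gy (-3.29 and -2.36). Csf1r, the receptor of monocyte growth factor, and Ncr1, a receptor of NK cells, passed in no comparison (limma).

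**Figure D2:**
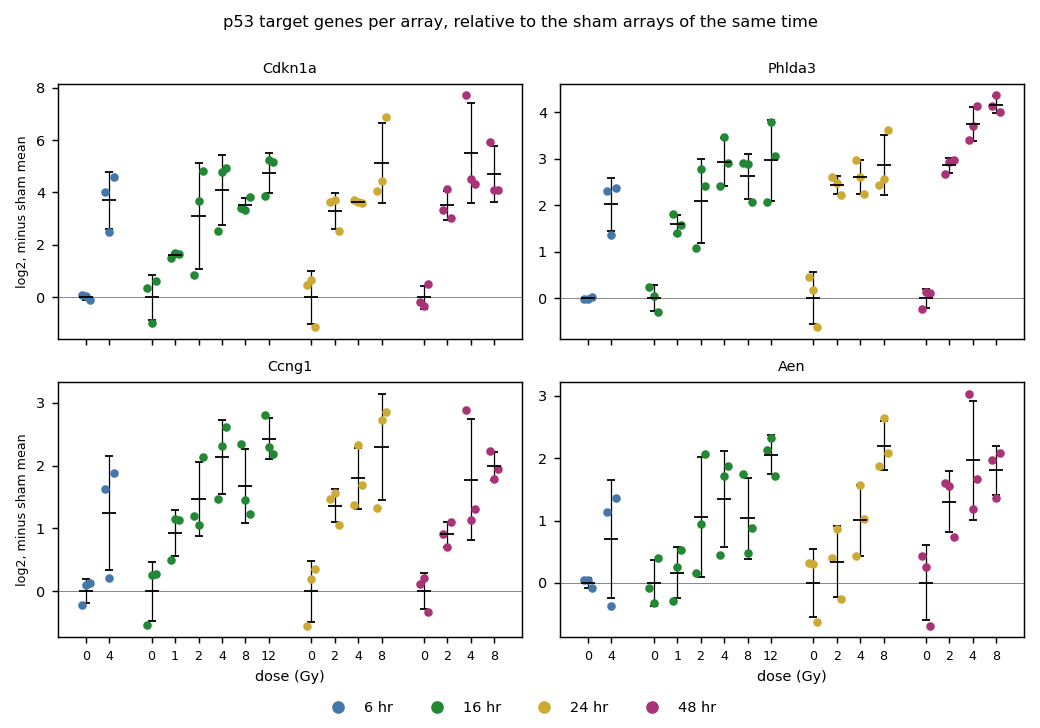
Log2 expression of Cdkn1a, Phlda3, Ccng1 and Aen per array (points), centred on the sham mean of each time, against dose in Gy at 6, 16, 24 and 48 hr, with bars for the mean and SD of 3 mice. Phlda3 lay 4.16 above the shams at 48 hr after 8 Gy.

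Over the 24 lists and 12 comparisons, 137 of 288 set tests passed with a preset correlation of 0.01, and 2 of these held with a correlation estimated from the data, the oxidative stress list at 6 hr and the B cell list at 16 hr after 12 Gy. Circadian clock genes were called in none of the 12 (medians -0.98 to 0.63, smallest adjusted p = 0.144), nor were dendritic cell markers (medians -1.23 to 0.05, smallest adjusted p = 0.156), although Irf8 (-3.19) and Ly6d (-5.11), which B cells also express, fell at 6 hr. With genes at their bounds the medians of other called lists moved by over 1.5 times. At 6 hr progenitor, oxidative stress and immediate-early genes had 0.03, 0.13 and 0.00. At 16 hr proliferation genes had -0.32, -0.48 and 0.17 at 2, 4 and 12 Gy, and progenitor genes 0.03, 0.00 and 0.34 at 2, 8 and 12 Gy. NK genes had 0.09 and -0.42 and inflammatory genes 0.05 and 0.19 at 4 and 12 Gy, p53 and monocyte genes 0.00 and 0.09 at 2 Gy and immediate-early genes 0.05 at 4 Gy. At 24 hr repair genes had -0.52 and -0.17 at 2 and 4 Gy, eosinophil and progenitor genes 0.20 and 0.00 at 2 Gy, interferon genes 0.47 at 4 Gy, and p53, NK and granule genes 0.39, -0.06 and 0.59 at 8 Gy. At 48 hr p53 genes had 0.15 and 0.41 and apoptosis genes 0.13 and 0.43 at 2 and 8 Gy, glucocorticoid genes 0.38 and 1.07 at 2 and 4 Gy, NK and progenitor genes 0.34 and 0.00 at 2 Gy and inflammatory genes 0.18 at 4 Gy. Platelet and neutrophil lists were called up in all 12, and B cell, T cell, MHC class II and ribosomal lists down in 11 each.

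Markers of further tissues and cell types, some of which blood cells also express, were measured with 10 lists chosen after the data were seen. Many members were near background, so their means, and T and B cell means of single arrays, have 1 floor for all arrays compared. Cardiac muscle markers lay above the other 2 arrays of the group by 6.14 on the 48 hr 8 Gy replicate 3 array, 5.07 on the 48 hr 4 Gy replicate 3 array, and 2.69 on the 16 hr 8 Gy replicate 3 array. Among shams the 16 hr replicate 1 array lay 1.63 above. Markers of serous cavity macrophages lay 5.71 above on the 48 hr 8 Gy replicate 1 array, 4.12 on the 16 hr 2 Gy replicate 3 array, 3.65 on the 6 hr 4 Gy replicate 3 array and 3.03 on the 6 hr sham replicate 1 array. Airway epithelium markers lay 8.00 above on the 48 hr 4 Gy replicate 1 array, and liver markers 9.69 on the 48 hr 2 Gy replicate 2 array and 4.85 on the 16 hr sham replicate 3 array. The means of the 12 irradiated groups minus their shams ranged over -0.47 to 2.53 for cardiac, -0.12 to 0.60 for further cardiac and -0.28 to 0.24 for skeletal muscle lists. They ranged over -1.61 to 4.55 for macrophage, 0.10 to 2.63 for further macrophage, -0.78 to 0.54 for B-1 cell, -3.95 to -0.37 for B-2 cell, -0.39 to 2.41 for airway, -1.71 to 2.57 for liver and -1.43 to -0.59 for thymocyte lists. The monocyte list shares Fn1 and the platelet list Selp and F5 with the macrophage lists. The sources used here do not say how blood was drawn.

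**Figure D3:**
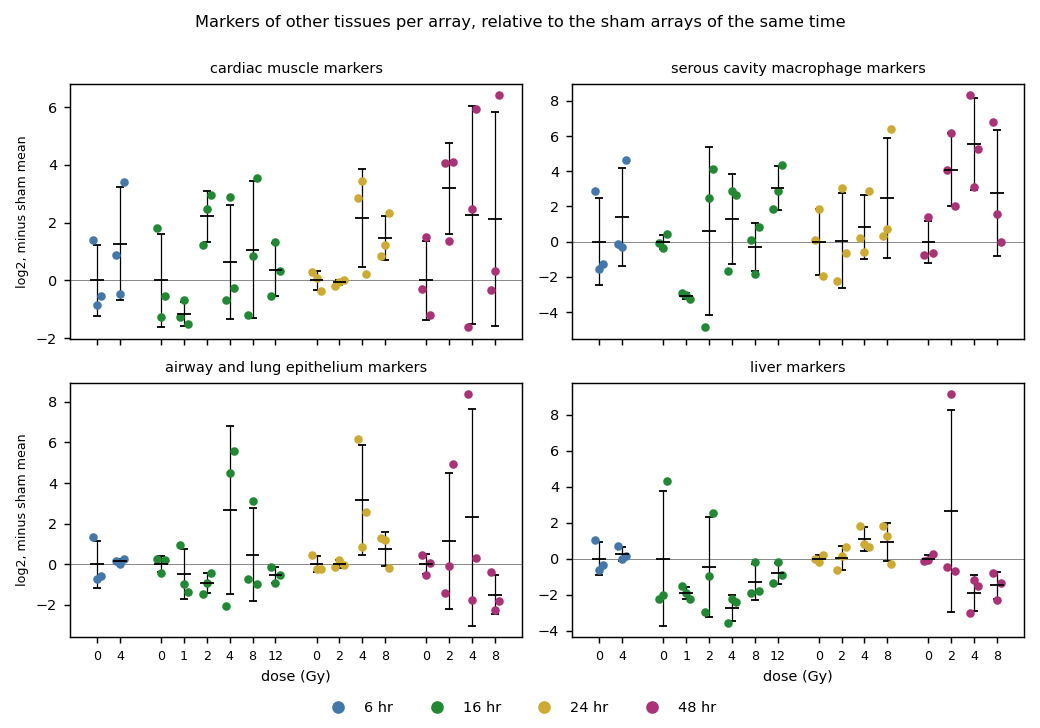
Mean log2 expression of cardiac muscle, serous cavity macrophage, airway epithelium and liver markers per array (points), centred on the sham mean of each time, against dose in Gy at 6, 16, 24 and 48 hr, without a floor. Single arrays stood far above the rest of their group, by 9.09 for airway markers at 48 hr after 4 Gy and 9.72 for liver markers at 48 hr after 2 Gy.

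In simulated data with the spread of these arrays, the test recovered 0% and 17% of genes changed 2-fold and 4-fold for the 6 hr comparison, 0% and 20% for 16 hr after 8 Gy, 0% and 26% for 24 hr after 8 Gy and 1% and 21% for 48 hr after 8 Gy. It recovered 6% and 52%, 2% and 41% and 0% and 23% for the dose slopes at 16, 24 and 48 hr, 0% and 16% for the difference between 48 and 24 hr and 0% and 1% for that between 16 and 6 hr. Of its calls 3 (13%) were false for 16 hr after 8 Gy and 1 (5.88%) for the 48 against 24 hr difference. Others had 0% to 4.44%. Correlated genes were not simulated.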

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

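The exchange of the planned scaling over all probes for that over detected probes and normexp background correction were chosen after seeing the data, and the test of the difference itself was not. The effect of irradiation, as the mean of 2, 4 and 8 Gy minus sham, differed between 48 and 24 hr for 2806 genes (limma), 641 higher and 2165 lower at 48 hr. Among named genes the difference, on the log2 scale, was Chd4 2.70, Lpp 2.71, Terf2 2.94, Ppfibp1 2.76 and Pdk2 3.26 upward, at adjusted p from 0.0103 to 0.0111. Downward it was Cdc25b -3.22, Lig1 -3.65, Pstpip2 -2.92, Ogfod1 -2.83 and Ralgps1 -2.83, each at adjusted p = 0.0103, and -2.46 for Alas2 (adjusted p = 0.0324). Ppfibp1 and Pdk2 were not well above background in the 48 hr shams, and with normexp turned to -0.24 and -0.23. These genes were singled out because a test of the difference between the times passed. The count was 0 without 48 hr sham replicate 3, and with scaling over all probes 623 genes were higher and 309 lower, so neither the number nor its balance is fixed. The times lay on separate slides, and no explanation of the difference was tested. No test of single outlying arrays was made in these groups of 3.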

How the results depend on the processing

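The exchange of the 2 scalings, normexp background correction, setting aside 3 arrays, marker means as covariates, and the list tests with the slide as a block or over genes above background on all arrays were chosen after seeing the data, and so was the comparison of other splits with doses and slides. Counts that moved by over 1.5 times follow by alternative, and every count not listed under an alternative that was run stayed within 1.5 times. The cause was not tested in any of these cases, beyond what an alternative changes by its construction. Quantile normalization gave 538 for 6 hr 4 Gy, 10 for 16 hr 2 Gy, 40 for 16 hr 4 Gy, 427 for 16 hr 12 Gy and 1395 for the 16 hr slope. Later times had 3224 for 24 hr 4 Gy, 1964 for 24 hr 8 Gy, 1519 for the 24 hr slope and 1366 for the 48 against 24 hr difference. The 75th percentile over all probes gave 2 for 16 hr 2 Gy, 293 for 16 hr 12 Gy and 9 for the 16 against 6 hr difference. Later times had 1016 for 24 hr 8 Gy, 708 for the 24 hr slope and 932 for the 48 against 24 hr difference. Testing dim probes too, so more genes, gave 658 for 6 hr 4 Gy, 10 for 16 hr 4 Gy, 1531 for 16 hr 8 Gy, 117 for 16 hr 12 Gy and 277 for the 16 hr slope. Later times had 110 for 24 hr 2 Gy, 451 for 24 hr 4 Gy, 300 for 24 hr 8 Gy, 1614 for 48 hr 2 Gy, 20551 for 48 hr 4 Gy, 22774 for 48 hr 8 Gy, 156 for the 24 hr slope, 20724 for the 48 hr slope and 16847 for the 48 against 24 hr difference. Testing only genes well above background on all arrays of a compared group, so fewer genes, gave 8 for 16 hr 2 Gy, 272 for 16 hr 4 Gy, 389 for 16 hr 12 Gy, 2452 for 24 hr 2 Gy and 1023 for the 16 hr slope. With only the compared groups in the fit, so fewer arrays for the spread, there were 3551 for 6 hr 4 Gy, 2 for 16 hr 1 Gy, 0 for 16 hr 2 Gy, 0 for 16 hr 4 Gy, 4969 for 16 hr 8 Gy and 212 for the 16 hr slope. Later times had 4440 for 24 hr 2 Gy, 3855 for 24 hr 4 Gy, 53 for 24 hr 8 Gy and 7171 for 48 hr 2 Gy. The slide as a block gave 4833 for 6 hr 4 Gy, 297 for 16 hr 1 Gy, 0 for 16 hr 2 Gy, 467 for 16 hr 4 Gy, 6026 for 16 hr 8 Gy, 709 for 16 hr 12 Gy, 2155 for the 16 hr slope and 302 for the 16 against 6 hr difference. Later times had 4720 for 48 hr 8 Gy and 4323 for the 48 hr slope. Array weights gave 15667 for 6 hr 4 Gy, 673 for 16 hr 1 Gy, 0 for 16 hr 2 Gy, 3177 for 16 hr 4 Gy, 6409 for 16 hr 8 Gy, 7006 for 16 hr 12 Gy, 7187 for the 16 hr slope and 9062 for the 16 against 6 hr difference. Later times had 8202 for 24 hr 2 Gy, 8892 for 24 hr 4 Gy, 9946 for 24 hr 8 Gy, 10078 for 48 hr 2 Gy, 13946 for 48 hr 4 Gy, 13002 for 48 hr 8 Gy, 9034 for the 24 hr slope and 10401 for the 48 against 24 hr difference. The trend and robust options gave 3 for 16 hr 2 Gy, 187 for 16 hr 4 Gy and 847 for the 16 hr slope. The mean of the kept probes gave 2 for 16 hr 2 Gy. The authors' scaled values gave 1929 for 6 hr 4 Gy, 31 for 16 hr 4 Gy and 5679 for 48 hr 8 Gy. Dose as log2 of Gy plus 1 gave 1269 for the 16 hr slope and 1387 for the 24 hr slope. Normexp background correction gave 13 for 16 hr 2 Gy, 224 for 16 hr 4 Gy, 1295 for 16 hr 8 Gy, 55 for 16 hr 12 Gy and 121 for the 16 against 6 hr difference. Later times had 32 for 24 hr 2 Gy, 258 for 24 hr 4 Gy, 100 for 24 hr 8 Gy, 5135 for 48 hr 2 Gy, 13489 for 48 hr 8 Gy, 48 for the 24 hr slope, 12684 for the 48 hr slope and 9215 for the 48 against 24 hr difference. Without 24 hr 8 Gy replicate 3, 48 hr 4 Gy replicate 1 and 16 hr 12 Gy replicate 2 there were 183 for 16 hr 4 Gy, 311 for 16 hr 12 Gy and 1125 for the 16 hr slope. Later times had 5554 for 24 hr 2 Gy, 5726 for 24 hr 4 Gy, 6105 for 24 hr 8 Gy, 6157 for 48 hr 2 Gy, 5320 for the 24 hr slope and 6251 for the 48 against 24 hr difference. Cardiac and macrophage marker means as covariates gave 5611 for 6 hr 4 Gy, 0 for 16 hr 2 Gy, 388 for 16 hr 4 Gy, 2378 for 16 hr 12 Gy and 4441 for the 16 hr slope. Later times had 3379 for 24 hr 2 Gy, 3604 for 24 hr 4 Gy, 2832 for 24 hr 8 Gy, 1340 for 48 hr 2 Gy, 4872 for 48 hr 4 Gy, 1480 for the 24 hr slope and 1086 for the 48 against 24 hr difference. With an estimated correlation the list tests gave 2 for list calls.

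Leaving out each array in turn gave counts of 405 to 1053 for 6 hr 4 Gy, 0 to 3 for 16 hr 1 Gy, 0 to 22 for 16 hr 2 Gy, 7 to 82 for 16 hr 4 Gy, 199 to 2111 for 16 hr 8 Gy and 52 to 311 for 16 hr 12 Gy. They were 50 to 1289 for 24 hr 2 Gy, 206 to 1146 for 24 hr 4 Gy, 202 to 3631 for 24 hr 8 Gy, 924 to 2777 for 48 hr 2 Gy, 5771 to 7761 for 48 hr 4 Gy and 6571 to 7995 for 48 hr 8 Gy. The slopes, time differences and lists had 166 to 1474 for the 16 hr slope, 150 to 2619 for the 24 hr slope, 5835 to 9377 for the 48 hr slope, 0 to 4847 for the 48 against 24 hr difference, 0 to 191 for the 16 against 6 hr difference and 129 to 144 for list calls. Over the 288 list tests, leaving out an array kept the direction and the side of the threshold in 1620 cases, lost a call in 64 and gained one in 41. For the named genes these were 4101, 303 and 30.

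Directions turned in few cases, and the cause was not tested. With normexp the fall of Cd160 at 6 hr went to 0.22, the rise of Psrc1 at 48 hr after 8 Gy to -0.42, and the upward differences between 48 and 24 hr to -0.24 for Ppfibp1 and -0.23 for Pdk2. Cd160 was not well above background on any irradiated array, nor the others on any 48 hr sham, so their sizes are not fixed. With quantile normalization Pf4 at 48 hr after 4 Gy went from -0.22 to 1.36. The direction of the set test turned for erythroid markers at 16 hr after 2 Gy without 2 Gy replicate 3 (median -0.223). It also turned for proliferation genes (median 0.081) and inflammatory genes (median 0.125) at 16 hr after 12 Gy without 12 Gy replicate 2, and with the 3 arrays set aside. Leaving out each array gave medians of -1.01 to -0.223, 0.081 to 0.512 and 0.125 to 0.73 for these lists. The normexp correction on the mean signal that had been planned was not run, since that column is not used here, and the median signal took its place. Genes that are dim sit at a floor that moves with the brightness of the array, so bounds and the counts over genes above background on all arrays are given beside the main ones.

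The labels give replicate numbers, and not every same-numbered pair of arrays deviated from its group means together. The correlation of such deviations across genes ran from -0.579 to 0.796 at 24 and 48 hr (median 0.056) and from -0.534 to 0.724 at 6 and 16 hr (median 0.073). It was over 0.1 in 38 and 36 of 84 pairs, and the own number was the best match in 35 and 42, where chance gives 28. The numbers are therefore not read as pairs. The replicate block gave 1982 for 6 hr 4 Gy, 291 for 16 hr 12 Gy and 979 for the 16 hr slope, and moved no other count by over 1.5 times. Of the 137 list calls 136 remained with the block, all but that of proliferation genes at 16 hr after 12 Gy.

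For 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The highest count of another split, beside the real count in parentheses, was 0 for 16 hr 1 Gy (0), 16 hr 8 Gy (2769), 24 hr 2 Gy (1291), 24 hr 4 Gy (2003), 24 hr 8 Gy (648), 48 hr 2 Gy (2790) and 48 hr 8 Gy (8648), 1 for 16 hr 2 Gy (1), 2 for 6 hr 4 Gy (1244), 16 hr 4 Gy (95) and 16 hr 12 Gy (189) and 41 for 48 hr 4 Gy (7384). As many genes as in the real split came from 10 of 10 splits at 16 hr 1 Gy, 2 at 16 hr 2 Gy and 1, the real one, elsewhere. Unadjusted shares of splits were under 0.05 for the slopes and the 48 against 24 hr difference. An effect of slide stays open, since the splits ignored it. The real doses had 0.429 and 0.51 of their variance between slides at 16 and 48 hr. As many genes came from 4 of 100 splits for the 16 hr slope, 2 for the 24 hr slope, 1 for the 48 hr slope and 1 for the 48 against 24 hr difference. The highest other split gave 4116, 440, 7228 and 2269, and the real one 544, 407, 8182 and 2806. At 16 hr that is several times the real count, in a split whose doses had a Pearson r of 0.144 with the real ones and 0.272 of their variance between slides. This points to a structure of the samples, which was not identified. The 24 hr split with 440 had r of -0.105 and 0.7 of its dose variance between slides, where the real doses had 0, and with the slide as a block the 24 hr slopes passed for 282 rising and 267 falling genes. For the 16 against 6 hr difference all 100 of 100 splits gave at least the real count of 0, up to 117.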

Other observations

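The tissue lists, their floor and the choice of arrays to look at were made after the data were seen, as were the tests of a shared cardiac effect, of B-1 cells, of wrong labels and of thymus. On single arrays marker genes of liver and airway reached high levels. On the 48 hr 2 Gy replicate 2 array the plasma protein genes Apoa2 and Ahsg lay 5.20 and 9.18 (log2) above the highest 48 hr sham and Serpina1a, not well above background on any sham, at least 10.85. On the 48 hr 4 Gy replicate 1 array the airway secretory genes Scgb1a1 and Scgb3a1 lay 8.18 and 8.73 above it and Bpifa1, not well above background on any sham, at least 9.02. Of these, Ahsg, Scgb1a1 and Scgb3a1 were well above background on 1 of 3 shams.

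Cardiac muscle transcripts were high on single arrays of irradiated and sham groups, with Myl2 at 3.35 and Fabp3 at 1.82 on the 48 hr 8 Gy replicate 3 array. Without a floor the marker mean ranged over 7.54 within a 48 hr irradiated group, against 2.71 over shams and a mean effect of 2.53. This argues against a shared irradiation effect as the whole cause. A shared part stays open. Heart tissue carried into the blood sample is a candidate source, as the further cardiac markers, not looked at before, moved with the first within groups (r = 0.903 in both versions). Less blood RNA over a constant carry-over stays open, with r of -0.26 and 0.062 between the cardiac mean and array brightness, and a first bound of r at 0 or above was replaced by an interval above 0 after 0.062 was seen, since that r lies within its spread of 0. Of the 16 cardiac markers, 2 and 7 were above background in a sham group of the versions and 1, Cox6a2, is in another list, and the labels name no sort that would remove other cells.

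Markers of serous cavity macrophages were high on single arrays, with Saa3 at 5.09 and Fn1 at 3.93 on the 24 hr 8 Gy replicate 3 array, where the B cell and B-1 means lay 1.18 and 0.89 above the other arrays of the group at a common floor. Unirradiated mice are argued against in arrays at 4 Gy or more, of which 0 reached the lowest sham of their time in B-2 markers. Other label swaps were not tested. A shared source of macrophage transcripts is a candidate, as 10 further markers moved with the first (r = 0.958 and 0.975). Of the 10, Selp, F5 and Lyz1 are in earlier lists. Cells of a serous cavity stay open: B-1 markers moved with them over irradiated arrays (r = 0.884 and 0.846, against 0.369 and 0.545 for B-2 markers, and 0.606 and 0.729 against 0.101 and 0.458 with the floor), but 2 of the 4 B-1 markers had been seen on such arrays before the test, and at 16 hr after 12 Gy, with macrophage markers above all shams on 3 of 3 arrays, B-1 markers lay -0.68 from the shams with the floor. Of the 14 macrophage markers 8 and 9 were above background in a sham group and 2 are in another list, and an irradiation effect on blood monocytes was not tested.

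T cell transcripts were high on the 16 hr 12 Gy replicate 2 array, where Cd3e was 1.33 against -3.30 and -3.80 on the other arrays of the group, and Lck 0.30 against -6.68 and -6.88. An unirradiated mouse is argued against, as the B-2 marker mean lay -4.21 from the lowest 16 hr sham, with the limit on B-2 markers given above. Other label swaps were not tested. Thymus carried into the blood sample stays open. Of the 4 thymocyte genes Rag1, Rag2, Ptcra and Dntt, 1 was well above background (Dntt at -3.80, with Rag2 at -7.09). Rag1 and Ptcra had no kept probe and so no value. The bound that would have argued against thymus was first set at 1 or fewer genes. It was lowered to 0 after this count was seen, because the mouse had received 12 Gy, which may remove such thymocytes. Of the 10 thymocyte markers 5 are in other lists and 6 and 7 were above background in a sham group, and no biological explanation was tested.

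The relations behind these patterns are Pearson r and Spearman rho of deviations from group means across arrays, 24 per version or 18 irradiated ones, with 2-sided permutation tests (100000 draws, smallest p 1e-05) adjusted over 10 relations. The last r of each leaves out the 2 farthest arrays. Cardiac against further cardiac markers gave r = 0.903, p = 0.00511, adjusted 0.0102, rho = 0.708, p = 0.00843, last r = 0.822 at 24 and 48 hr. At 6 and 16 hr it gave r = 0.903, p = 1e-04, adjusted 0.000333, rho = 0.875, p = 4e-05, last r = 0.855. Array brightness against cardiac markers gave r = -0.26, p = 0.242, adjusted 0.269, rho = -0.284, p = 0.261, last r = -0.55 at 24 and 48 hr. At 6 and 16 hr it gave r = 0.062, p = 0.818, adjusted 0.818, rho = 0.046, p = 0.859, last r = 0.115. Macrophage against further macrophage markers gave r = 0.958, p = 1e-05, adjusted 5e-05, rho = 0.937, p = 2e-05, last r = 0.938 at 24 and 48 hr. At 6 and 16 hr it gave r = 0.975, p = 1e-05, adjusted 5e-05, rho = 0.969, p = 1e-05, last r = 0.954. Macrophage against B-1 markers gave r = 0.884, p = 0.00277, adjusted 0.00692, rho = 0.777, p = 0.00545, last r = 0.808 at 24 and 48 hr. At 6 and 16 hr it gave r = 0.846, p = 0.00814, adjusted 0.0136, rho = 0.833, p = 0.0102, last r = 0.724. Macrophage against B-2 markers gave r = 0.369, p = 0.201, adjusted 0.251, rho = 0.265, p = 0.394, last r = 0.39 at 24 and 48 hr. At 6 and 16 hr it gave r = 0.545, p = 0.186, adjusted 0.251, rho = 0.362, p = 0.269, last r = 0.147.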
